A study of Drosophila melanogaster with 6 samples.

How the data were processed

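Whole-body RNA of adult w1118 females on RD or HFD was measured on 6 Affymetrix arrays, 3 per diet, with samples grouped by their titles in the labels. The deposited values are linear intensity values per probe set, made with MAS5, whose version is not given in the sources used here, per the submitters' processing notes. MAS5 summarises the probes of a set into 1 signal and usually scales each array to a common mean; the 2% trimmed mean was 327 to 343 over the 6 arrays. The labels' protocols name Trizol extraction with an RNeasy cleanup. From 101 to 121 values per array were 0. No column of the table was of a sample not listed here.

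The choices of test, filter, gene lists and alternatives were made before the data were examined, except where the text says otherwise. The AFFX controls were left out, 1 was added to each signal before log2, and probe sets were kept where the mean over 6 arrays lay above the 40th percentile of 18769 (log2 of 4.86), which left 11261 and removed 7508. No further normalization was applied. Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 11261 probe sets and a threshold of 0.05. The fits without 1 array used the probe sets kept over all 6. Standard errors are those of the moderated fit. Low signals are noisy: with the tested probe sets in 4 groups by signal, the median SD within a diet was 0.21 on the log2 scale in the dimmest group and 0.074 in the brightest, and fold changes of dim probe sets are understated by the added 1. No detection calls were used here.

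Gene names came from the array annotation supplied with the table: 13647 probe sets had 1 gene symbol, 402 several and 4720 none here, and 13544 of those with 1 matched the reference table of Release 6 genes by gene ID with the same symbol. No coordinates are given, since the annotation names no build; the genomic span of genes was taken from the reference table for 99.6% of tested genes. The 37 gene lists, of pathways, gene families and markers of fly tissues, had 997 members, of which 868 were named on the array and 691 tested; the others are unnamed here or under the filter. A list was tested with camera (preset correlation 0.01, probe set with the highest mean signal per gene) where at least 5 members were tested, 35 lists in all, which left out the digestive lysozymes and the Turandot genes, with Benjamini-Hochberg adjustment over the lists. Of 10 lists past 0.05, none passed with an estimated correlation between genes, where the smallest adjusted p was 0.23, and fry, which tests whether the genes of a list move 1 way on balance, passed 11 lists. The counts adjusted over the list alone use the same p-values.

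Genes were named by a fixed rule over probe sets with 1 gene: the 14 largest rises and the 14 largest falls past the threshold whose HFD arrays all lay above or all below the RD arrays, up to 4 members past the threshold per list by absolute log2 fold change, or the 2 with the smallest p where none passed, and 13 background genes whatever their result. Of these, 8 were tested: Yp1, Yp2, Yp3, bmm, FASN1, Ilp2, Act88F and RpL32; the others were not analysed here. Of 144 named genes, 8 had several tested probe sets, and these had the same sign. For Sod3, GstE9, tim and exu only 1 of 2 probe sets passed the threshold, and for Sh 3 of 4 did. Named outside the rule, to complete a list, were Mal-A5, Lpin, Gpdh1, cry and cyc, and, after their values were seen, Mtk and DptB.

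The fit and the list test were tested on simulated data for this comparison, with 200 of 11261 probe sets changed. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 71.6%, 100% and 100% of the changed probe sets, and 4.2% of the calls were false. A list shifted by 0.5 was called, and no other list of the 35 was. The SD of the simulated noise depended on signal alone, so these shares hold for such noise only. The simulated noise was independent between probe sets, while the estimated correlation within the muscle and neuron lists was 0.60. The simulation therefore cannot show false calls that come from correlation between genes or from differences of whole arrays. Alternatives were quantile normalization, median centring, adding 16 or 50, no filter or a filter at the 60th percentile, eBayes without a trend or robust, array weights, the replicate number as a block, leaving out each array, other thresholds and other list tests. After seeing the data, 2 were added: the mean log2 3'/5' ratio of the actin, GAPDH and eIF-4a controls as a covariate, and leaving out RD array 1 and HFD array 1 together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.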

Results

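Whole adult female flies of the w1118 strain were kept for 1 week on a regular diet (RD) or on a high-fat diet (HFD) made by adding coconut oil at 20% weight per volume, in normal oxygen, and were frozen at an age of 10 to 12 days. RNA of whole bodies was hybridised to Affymetrix Drosophila arrays, 3 per diet, and each array gave MAS5 signals for 18952 probe sets, 183 of them controls. The median signal was 52.8 to 55.3 on the RD arrays and 60.7 to 63.8 on the HFD arrays. Pearson's r across probe sets, on log2 signals, was 0.977 to 0.986 between arrays of a diet and 0.972 to 0.980 between diets, and no pair of arrays was a duplicate. Across probe sets, the first principal component held 61.4% of the variance and separated the diets; RD array 1 lay nearest to the HFD arrays on it. Nothing in the labels says whether the 3 samples of a diet were separate vials of flies, so p-values measure only the spread between these samples. Signals are given as mean ± SD with n = 3 per diet, and log2 fold changes, HFD minus RD, on the log2(signal + 1) scale with the standard error of the limma fit; the number of arrays limits their precision.

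The comparison of HFD with RD asks which transcripts of the adult female differ after a week on added fat. Of the named genes with all 6 signals above the level of the filter on dim probe sets, Jon25Bi, CG34166 and Gnmt fell most by fold change. Larval serum protein 2 (Lsp2), a storage protein made by the fat body, had a signal of 1194 ± 575 in RD and 17.3 ± 2.71 in HFD. Its 3 HFD signals lay below that level, so the size of its fall was not measured. The signal of the lysosomal mannosidase gene LManIII was 321 ± 104 in RD and 30.5 ± 17.3 in HFD, with 1 of the 3 HFD signals below the level, so its fold is not given either. The digestive protease gene Jon25Bi fell 10.7-fold, with a signal of 4278 ± 958 in RD and 397 ± 57.6 in HFD, and CG34166 fell 7.81-fold. Glycine N-methyltransferase (Gnmt), which consumes S-adenosylmethionine, fell 7.76-fold. Among the genes that rose, the signal of CG4702 was 24.9 ± 18.3 in RD and 163 ± 102 in HFD, and that of the ecdysone-inducible gene ImpE2 was 31.8 ± 10.2 in RD and 139 ± 63.2 in HFD. No fold is given for these 2 genes, since at least 1 RD signal of each lay below the level of the filter. The small heat shock protein gene l(2)efl rose 2.70-fold, with a signal of 1124 ± 98.0 in RD and 3034 ± 289 in HFD.

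**Figure D1:**
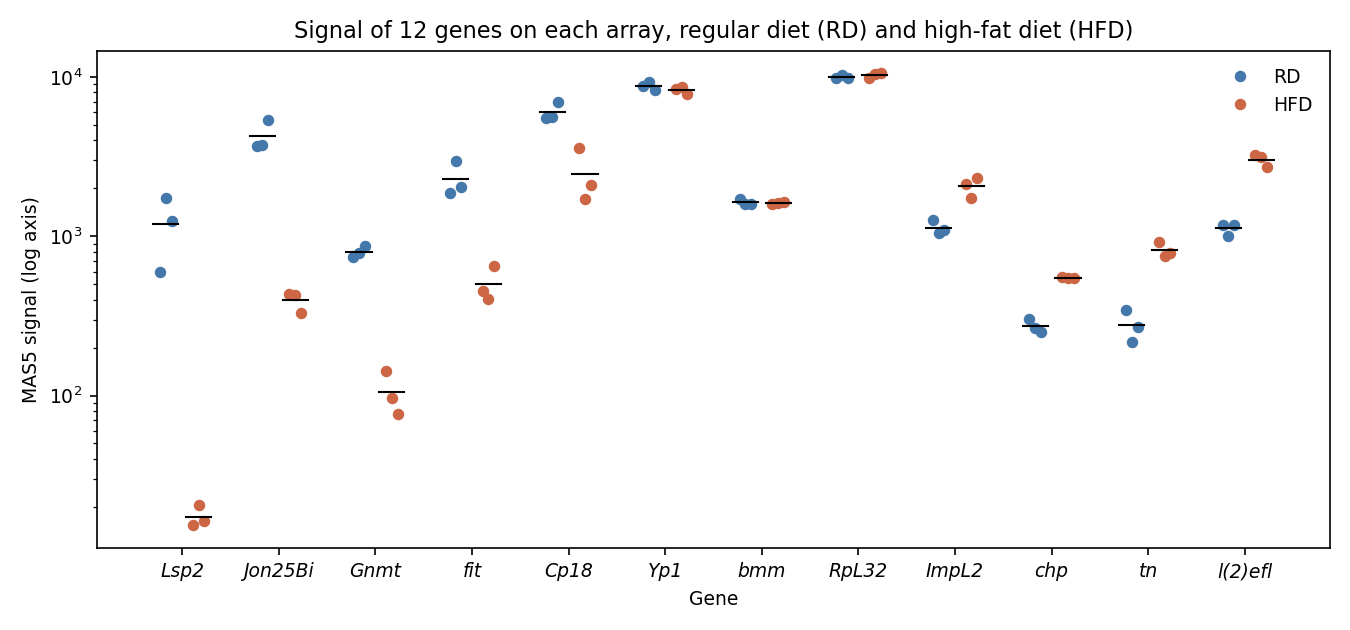
Signals of 12 genes on the 6 arrays, with MAS5 signal on a log axis, 1 dot per array and a black line at the mean of the 3 arrays of a diet. The HFD arrays of Lsp2 sit between 15.3 and 20.4, below the 3 RD arrays, while those of bmm and RpL32 overlap the RD arrays.

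Of the 11261 probe sets tested, 2196 passed an adjusted p of 0.05 (limma), 1449 of them higher and 747 lower in HFD, and 4003 had an unadjusted p under 0.05. Of the 2196, 212 were at least 2-fold higher and 78 at least 2-fold lower. The 3 HFD arrays lay all above or all below the 3 RD arrays for 42.0% of the tested probe sets, against 10% by chance. The calls were 66.0% higher and 34.0% lower. After quantile normalization they were 52.0% and 48.0%. After centring each array on its median, which moved the median log2 fold change of the tested probe sets by -0.21, they were 19.5% and 80.5%. The array medians, taken over all probe sets before the filter, were 52.8 to 63.8, so this centring follows dim signals. In the main fit the median log2 fold change of the tested probe sets was 0.0083. The count was 1361 with a stricter filter on dim probe sets, 4995 with median centring, 6129 with array weights, and 290 when a 2-fold change was also asked for. It was 1338, 1008, 1310 and 1250 without RD array 2, RD array 3, HFD array 1 and HFD array 2; probe sets lower in HFD then numbered 358, 245, 348 and 338. With the 3'/5' signal ratio of the control transcripts in the model, an alternative chosen after seeing the data, the count was 266, 213 higher and 53 lower. Of 136 named genes past the threshold, 37 kept the call with that ratio in the model, among them Lsp2, Jon25Bi, Gnmt, CG4702 and l(2)efl but not ImpE2 (adjusted p = 0.0746), whose estimate did not shrink. Without RD array 1, 2 or 3 and HFD array 1, 2 or 3, 131, 103, 92, 97, 104 and 106 kept it. Lsp2, Jon25Bi, Gnmt, CG4702, fit, tn and l(2)efl kept call and direction in every alternative that held them.

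Some control probe sets differed with diet. The signal of the actin control's 3' probe set over its 5' probe set, which rises when the RNA or the labelled copy is shorter, was 6.15 ± 1.53 in RD and 8.86 ± 0.479 in HFD (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). RD array 1, at 7.85, was the RD array nearest to HFD. The same ratio of eIF-4a was 7.78 ± 2.09 in RD and 10.3 ± 0.806 in HFD and that of GAPDH 2.16 ± 0.235 and 2.42 ± 0.147, and both overlapped between diets (exact permutation p = 0.2 each). The bioB spike-in controls, bacterial transcripts added to each sample before hybridisation, had a signal of 282 ± 14.03 in RD and 477 ± 99.2 in HFD (exact permutation p = 0.1).

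**Figure D2:**
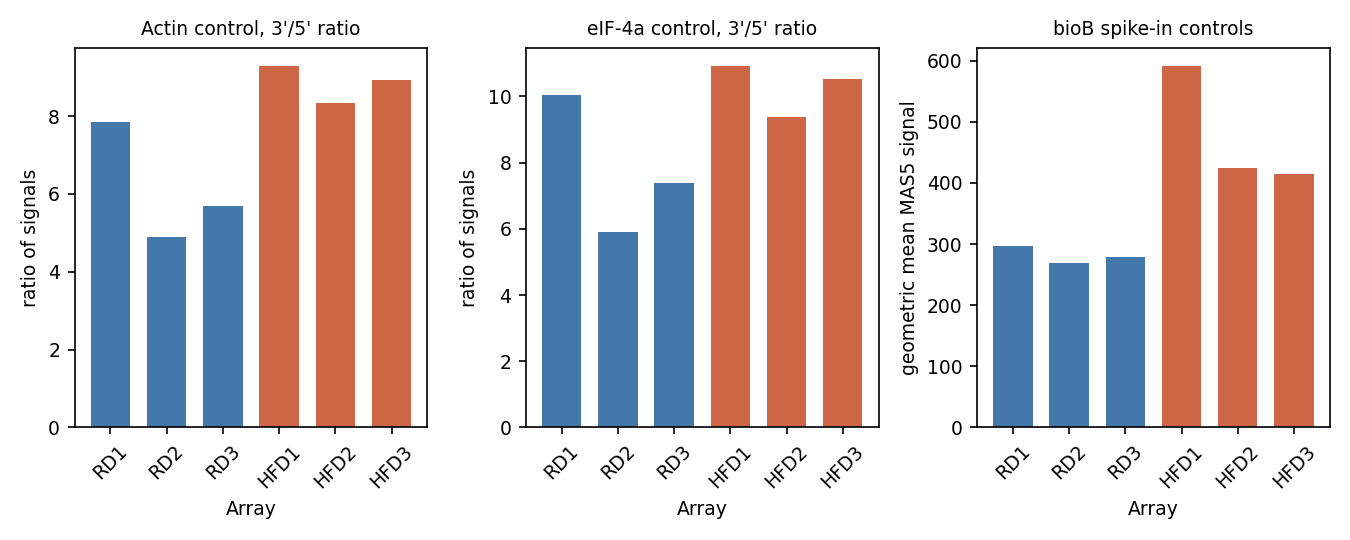
Control probe sets on each of the 6 arrays, with the 3'/5' signal ratio of actin and of eIF-4a and the geometric mean signal of the bioB spike-in controls, 1 bar per array. The bioB controls lie between 269 and 297 on the RD arrays and between 415 and 592 on the HFD arrays.

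Many genes of protein digestion fell, and some of carbohydrate digestion. Of 26 digestive serine protease genes tested, 16 fell and none rose, and 20 fell adjusted over the list alone. The median log2 fold change of the proteases was -0.50 (camera, adjusted p = 7.12e-12; adjusted p = 0.402 with an estimated correlation). Jon25Bi, Jon99Ci and Jon25Bii fell most, by 10.7-fold, 7.01-fold and 6.999-fold, and Jon66Ci fell 2.76-fold. These genes are close relatives, and a probe set may bind the RNA of more than 1 of them. With the control 3'/5' ratio in the model, 9 of the 26 fell (list median -0.45, adjusted p = 4.82e-14). Among 18 genes of carbohydrate digestion and sugar storage, 7 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone. The median of these carbohydrate genes was -0.24 (camera, adjusted p = 0.00434; adjusted p = 0.402 with an estimated correlation). The maltases Mal-A7 (-0.96 ± 0.21), Mal-A3 (-0.94 ± 0.14) and Mal-A6 (-0.86 ± 0.21) and the glucosidase gene tobi (-1.20 ± 0.35) fell on the log2 scale, and Mal-A5 rose (0.27 ± 0.054), while 10 of the 18 did not pass. Carbohydrate genes that rose and fell numbered 0 and 13 with median centring and 2 and 10 with array weights. The call of this list was lost with the stricter filter (adjusted p = 0.0571; 4.82e-04 to 0.402 over the alternatives), and not with the control 3'/5' ratio in the model, where no member passed (list median -0.20, adjusted p = 0.0342). Carbohydrate genes that rose numbered 0 without RD array 3, and those that fell numbered 2 without HFD array 1, 3 without RD array 2 or 3 and 4 without HFD array 2. Of 3 digestive lysozyme genes LysP rose (1.11 ± 0.18). Outside the lists, the lysosomal mannosidase genes LManIII, dim on the HFD arrays, and LManV (-1.91 ± 0.32) fell. With the control 3'/5' ratio in the model neither passed (adjusted p = 0.0572 for LManIII), and LManV was at -1.43 (adjusted p = 0.131).

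Called lipid genes went in both directions. Almost all of them went down with median centring, which moved the median of all tested probe sets by -0.21. In the list of lipid storage and lipolysis, 4 of 20 members fell and 1 rose, and 5 fell and 1 rose adjusted over the list alone. The median of the lipid storage list was -0.19 (camera, adjusted p = 0.0404; adjusted p = 0.402 with an estimated correlation). The members that fell, CG6296 (-1.53 ± 0.24), CG17192 (-0.97 ± 0.21), CG8093 (-0.85 ± 0.12) and CG18301 (dim on the HFD arrays), are predicted lipases. Lpin, a phosphatidate phosphatase of fat synthesis, rose (0.66 ± 0.077). The call of this list was lost under quantile normalization, median centring, the stricter filter, the control 3'/5' ratio, and without RD array 2, RD array 3, HFD array 2 or HFD array 3, with adjusted p of 0.0743, 0.0863, 0.439, 0.211, 0.0522, 0.0755, 0.0591 and 0.0528 (0.00598 to 0.439 over the alternatives). Lipid storage genes that fell numbered 2 without HFD array 2. The lipid storage median was -0.32 without RD array 1, -0.12 without RD array 2, -0.40 with median centring, -0.056 with the stricter filter and -0.051 with the 3'/5' ratio. The triglyceride lipase gene bmm did not pass, with a signal of 1637 ± 71.4 in RD and 1617 ± 25.1 in HFD (adjusted p = 0.836). Of 12 fatty acid synthesis genes, 4 rose and 2 fell, 4 rose and 5 fell adjusted over the list alone (list adjusted p = 0.434). FASN2 rose 2.05-fold, FASN3 and malic enzyme (Men) fell, by 0.62 and 0.46 on the log2 scale, and FASN1 did not pass (-0.22 ± 0.11, adjusted p = 0.172). With the control 3'/5' ratio in the model, 1 of the 12 rose (list median -0.036, adjusted p = 0.998). Fatty acid synthesis genes that rose numbered 1 without RD array 3 or HFD array 2 or 3, and those that fell numbered 4 without RD array 1. Beta-oxidation had 2 of 17 genes lower, Acox3 and yip2, also adjusted over the list alone (list adjusted p = 0.365). Lipid transport had 2 higher and 2 lower of 18, also adjusted over the list alone (list adjusted p = 0.312), with the sterol-binding Npc2d at -1.52 ± 0.27 and the lipoprotein apolpp at -0.52 ± 0.089. With the 3'/5' ratio in the model these 2 were at -1.20 (adjusted p = 0.149) and -0.33 (adjusted p = 0.132). Beta-oxidation genes that fell numbered 0 without HFD array 1 and 1 without RD array 2 or 3 or HFD array 2 or 3. Lipid transport genes that rose numbered 1 without RD array 3 or HFD array 1, 2 or 3. Lipid genes that rose and fell numbered 1 and 2 (beta-oxidation) with quantile normalization, 1 and 8 (synthesis), 0 and 11 (beta-oxidation), 1 and 12 (storage) and 1 and 10 (transport) with median centring, 4 and 4 (synthesis), 2 and 5 (beta-oxidation), 2 and 11 (storage) and 4 and 3 (transport) with array weights, and 0 and 0 (beta-oxidation), 1 and 1 (storage) and 1 and 0 (transport) with the control 3'/5' ratio in the model.

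Of 10 genes listed for the fat body, 4 fell, Lsp2, Gnmt, Ag5r2 and apolpp, and Ag5r rose, also adjusted over the list alone. Whether Ag5r and Ag5r2 mark that tissue was not tested. The median log2 fold change of the fat body list was -0.25 (camera, adjusted p = 0.00425; adjusted p = 0.402 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.0529) and the stricter filter (0.0710; 7.00e-04 to 0.402 over the alternatives). Fat body genes that rose and fell numbered 1 and 8 with median centring. Without HFD array 3 the fat body median was -0.17. The list shares 2 genes each with those of lipid storage and of amino acid metabolism. Beyond the lists, fit, a gene expressed in the head fat body of females, fell 4.55-fold, and smp-30 fell 3.51-fold.

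Genes of eggshell and yolk fell while germline genes as a list did not pass. Of 21 yolk, vitelline membrane and chorion genes, 14 fell and none rose, and 16 fell adjusted over the list alone. The eggshell and yolk median was -0.69 (camera, adjusted p = 1.44e-09; adjusted p = 0.231 with an estimated correlation). The chorion genes Cp18 and Cp16 fell 2.55-fold and 2.34-fold, Femcoat fell 2.33-fold and the vitelline membrane gene Vm32E 2.17-fold. The yolk protein gene Yp2 fell by 0.40 and Yp3 by 0.23 on the log2 scale, and Yp1 did not pass (-0.089 ± 0.057, adjusted p = 0.299). In RD the signals of Yp1, Yp2 and Yp3 were 8816 ± 511, 13328 ± 152 and 11988 ± 235, and the array maxima were 15306.5 to 16256. Whether fold changes keep their size at such bright signals was not tested. With the control 3'/5' ratio in the model, 2 of the 21 fell (list median -0.50, adjusted p = 1.46e-09). The eggshell and yolk median was -0.41 with array weights. Eggshell and yolk genes that fell numbered 9 without RD array 2 or 3. Of 22 germline genes, 2 rose and 3 fell, 3 rose and 5 fell adjusted over the list alone, with a median of -0.12 (camera, adjusted p = 0.0811). The gene bam was at -0.69 ± 0.10 and grk at 0.31 ± 0.068. The germline list passed with median centring (adjusted p = 0.0310), without the filter (0.0454) and without RD array 2 (0.0418; 0.0310 to 0.747 over the alternatives). Germline genes that rose numbered 0 without HFD array 2 or 3 and 1 without RD array 3 or HFD array 1, and those that fell numbered 1 without RD array 3 or HFD array 1 and 5 without RD array 1. Without HFD array 1 the germline median was -0.058. Germline genes that rose and fell numbered 0 and 15 with median centring, 2 and 12 with array weights and 0 and 0 with the control 3'/5' ratio in the model. Of 26 genes of male reproduction named on the array, 7 were tested, and none passed, nor did any adjusted over the list alone. They were listed as a check on mixed sexes, but a test between diets cannot show males present alike in both. Mst57Da was at -0.32 ± 0.25 (list adjusted p = 0.992); the list median was 0.028 while camera pointed down.

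Genes of muscle and of the nervous system rose together. Of 19 muscle genes, 15 rose and 1 fell, the glycerol-3-phosphate dehydrogenase gene Gpdh1, and 16 rose and 1 fell adjusted over the list alone. The muscle median was 0.94 (camera, adjusted p = 6.32e-10; adjusted p = 0.402 with an estimated correlation). The genes tn, Act88F, Obsc and sls, the last coding for a titin-like protein, rose 2.99-fold, 2.60-fold, 2.36-fold and 2.28-fold. Of 14 neuron genes, 11 rose and none fell, and 12 rose adjusted over the list alone. The neuron median was 0.86 (camera, adjusted p = 7.58e-08; adjusted p = 0.402 with an estimated correlation). The potassium channel gene Sh was at 1.13 ± 0.19, and the sodium channel gene para, with RD signals near the level of the filter, had a signal of 28.6 ± 3.94 in RD and 70.3 ± 3.42 in HFD. Of 8 head and photoreceptor genes, 7 rose, 8 adjusted over the list alone, with a median of 0.92 (camera, adjusted p = 5.94e-07; adjusted p = 0.402 with an estimated correlation), and the gene chp, a photoreceptor surface protein, had a signal of 272 ± 25.9 in RD and 548 ± 6.75 in HFD. On the HFD arrays the 3'/5' ratio was higher for the actin control, without overlap, and on average for eIF-4a and GAPDH. With the mean log2 ratio of these 3 controls in the model, 7 muscle, 3 neuron and 5 head and photoreceptor genes rose, and the median was 0.76, 0.62 and 0.59. With the stricter filter, 6 of the 8 neuron genes still tested rose.

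**Figure D3:**
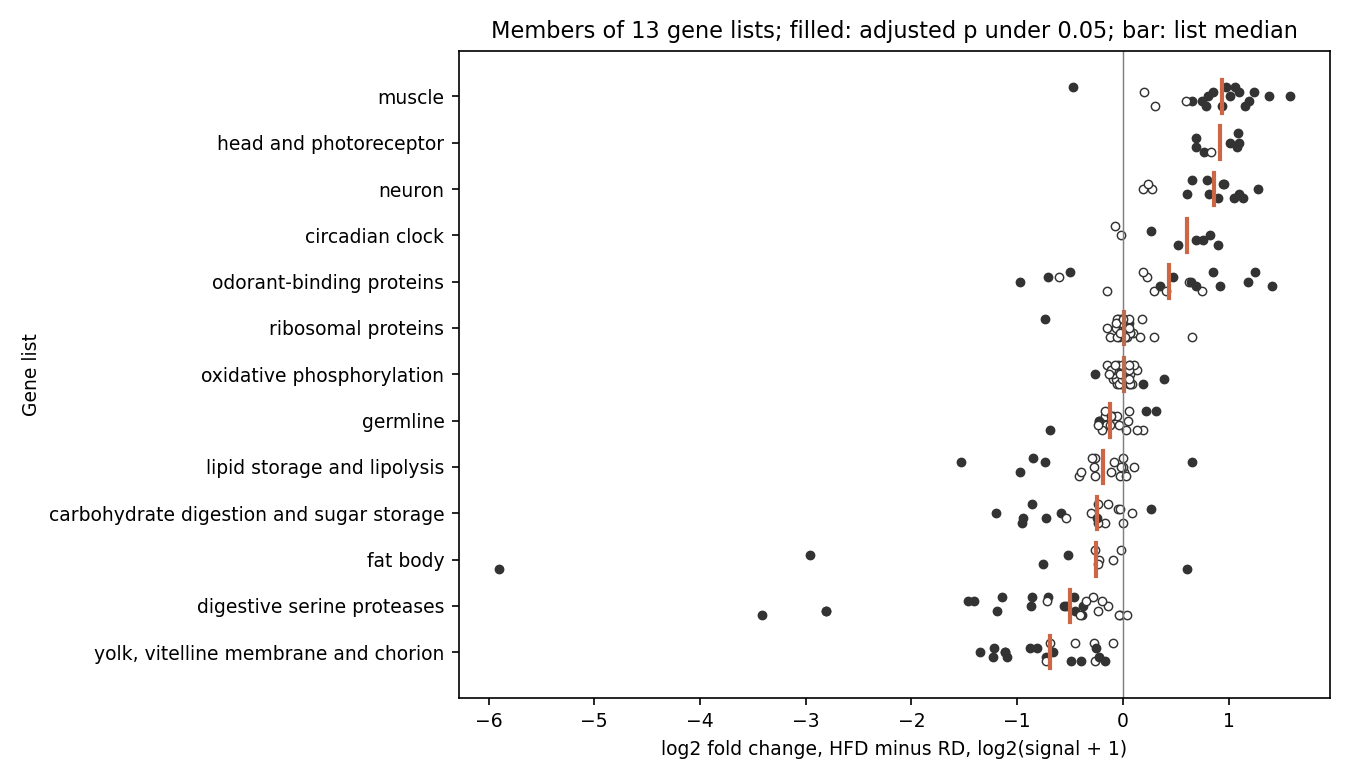
Log2 fold change, HFD minus RD, of each tested member of 13 gene lists, 1 dot per gene, filled where its adjusted p is under 0.05, with a bar at the median of the list. The medians run from -0.69 for eggshell and yolk genes to 0.94 for muscle genes.

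Clock genes, also expressed in neurons and photoreceptors, whose lists rose with medians of 0.86 and 0.92, were higher: 6 of 8 rose, with none lower, also adjusted over the list alone, and a median of 0.61 (camera, adjusted p = 0.0107; adjusted p = 0.484 with an estimated correlation). The genes per, vri, tim and Pdp1 were at 0.90, 0.83, 0.76 and 0.69, and cry and cyc did not pass. The time of day at freezing was not compared between diets. With the control 3'/5' ratio in the model no single clock gene passed, and the list did (list median 0.34, adjusted p = 0.00744). Clock genes that rose numbered 3 without RD array 3 or HFD array 1. With median centring, 4 rose and 1 fell, with a median of 0.40. Of 20 odorant-binding protein genes, 9 rose and 3 fell, 11 and 3 adjusted over the list alone (median 0.44, camera, adjusted p = 0.0389; adjusted p = 0.747 with an estimated correlation), with Obp56g at 1.41 ± 0.22 and Obp99a at -0.97 ± 0.17. That call was lost without the filter, with the stricter filter, with array weights, with fry and with cameraPR, and without RD array 1, RD array 2 or HFD array 2 (adjusted p = 0.194, 0.0522 and 0.0707; 7.92e-04 to 0.747 over the alternatives). It was lost too with RD array 1 and HFD array 1 both left out (adjusted p = 0.0776), and the median was 0.19 without the filter and 0.22 with array weights. Odorant-binding protein genes that rose numbered 5 without HFD array 3. Odorant-binding protein genes that rose and fell numbered 6 and 5 with median centring and 3 and 0 with the control 3'/5' ratio in the model.

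Of 16 genes of insulin, Akh and FOXO signalling, 6 rose and 1 fell, also adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.240). The insulin-like peptide gene Ilp2 rose 1.53-fold and ImpL2, which codes for a protein that binds insulin-like peptides, rose 1.81-fold, while Ilp8 fell 2.06-fold. With the control 3'/5' ratio in the model, 1 of the 16 rose (list median 0.10, adjusted p = 0.285). Ilp2, ImpL2 and Ilp8 did not pass there, at 0.50 (adjusted p = 0.192), 0.62 (adjusted p = 0.0517) and -0.66 (adjusted p = 0.0754). Insulin list genes that rose and fell numbered 4 and 4 with median centring and 9 and 4 with array weights. Immune effector genes had 2 of 17 higher and 1 lower, 3 and 1 adjusted over the list alone (list adjusted p = 0.209): Drs, coding for the antifungal peptide drosomycin, was at 0.51 ± 0.094. The immune effector list passed with median centring (adjusted p = 0.00813) and without HFD array 3 (0.0159; 0.00813 to 0.857 over the alternatives). Immune effector genes that rose numbered 1 without RD array 2 or HFD array 2, and those that fell numbered 0 without RD array 2 or 3 or HFD array 2 or 3. Of 21 immune recognition and signalling genes, 4 rose and 2 fell, 5 and 2 adjusted over the list alone (list adjusted p = 0.123). The complement-like gene Tep3 and the negative regulator pirk were at 0.80 ± 0.16 and 0.61 ± 0.10. The immune recognition list passed with fry (adjusted p = 0.0185), with median centring (0.0328) and with the mean of a gene's probe sets (0.0380; 0.0185 to 0.444 over the alternatives). Immune recognition genes that rose numbered 1 without RD array 3 and 2 without RD array 2 or HFD array 1 or 3, and those that fell numbered 1 without RD array 1, 2 or 3 or HFD array 1 or 3. Immune genes that rose and fell numbered 1 and 1 (effector) with quantile normalization, 3 and 4 (recognition) with median centring, 5 and 1 (effector) and 11 and 3 (recognition) with array weights, and 0 and 0 (effector) and 0 and 0 (recognition) with the control 3'/5' ratio in the model. Drs, Tep3 and pirk were then at 0.38 (adjusted p = 0.181), 0.49 (adjusted p = 0.237) and 0.50 (adjusted p = 0.129).

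The counts of ribosomal and energy genes depended on the scaling. Median centring, which follows dim signals, moved the median of all tested probe sets by -0.21. Of 40 ribosomal protein genes, 1 fell, RpL22-like (-0.74 ± 0.21), and none rose, with 0 past adjusted over the list alone and a median of 0.0075 (camera, adjusted p = 0.840). RpL32 had a signal of 9977 ± 214 in RD and 10300.0 ± 331 in HFD. The ribosomal list passed upward with quantile normalization (median 0.0401, adjusted p = 0.0236) and downward with median centring (median -0.20, adjusted p = 0.0373; 0.0236 to 0.984 over the alternatives). Ribosomal protein genes that rose numbered 1 without RD array 1 or HFD array 3, and those that fell numbered 0 without RD array 2 or 3 or HFD array 1, 2 or 3. Of 35 oxidative phosphorylation genes, 2 rose, ND-75 and ND-51, and 1 fell, COX7A, with 0 past adjusted over the list alone (median 0.0078, mean 0.0015, camera downward, adjusted p = 0.759). The oxidative phosphorylation list passed downward with median centring (adjusted p = 0.0162; 0.0162 to 0.969 over the alternatives). Oxidative phosphorylation genes that rose numbered 0 without RD array 3 or HFD array 1, 2 or 3 and 1 without RD array 1 or 2, and those that fell numbered 0 without RD array 3. The citric acid cycle had 4 of 15 higher, 6 higher and 1 lower adjusted over the list alone (list adjusted p = 0.272), with Ogdh at 0.45 ± 0.068. The citric acid cycle list passed with quantile normalization (adjusted p = 0.0495) and with the control 3'/5' ratio in the model (0.0365; 0.0365 to 0.814 over the alternatives), where no member passed and Ogdh was at 0.34 (adjusted p = 0.0929). Citric acid cycle genes that rose numbered 1 without RD array 2 or 3 or HFD array 2 or 3 and 2 without RD array 1, and those that fell numbered 1 without RD array 1. Ribosomal and energy genes that rose and fell numbered 4 and 1 (ribosomal) and 5 and 1 (oxidative phosphorylation) with quantile normalization, 0 and 25 (ribosomal), 0 and 19 (oxidative phosphorylation) and 1 and 6 (citric acid cycle) with median centring, 16 and 3 (ribosomal), 11 and 10 (oxidative phosphorylation) and 9 and 4 (citric acid cycle) with array weights, and 0 and 0 (ribosomal), 0 and 0 (oxidative phosphorylation) and 0 and 0 (citric acid cycle) with the control 3'/5' ratio in the model.

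Of 15 glycolysis and gluconeogenesis genes, 2 rose and 1 fell, 3 and 5 adjusted over the list alone (list adjusted p = 0.254), with the hexokinase genes Hex-A at 0.33 ± 0.10 and Hex-C at -0.43 ± 0.082. Glycolysis genes that rose numbered 0 without RD array 2 or 3 or HFD array 1, 2 or 3, and those that fell numbered 3 without RD array 1. Of 6 hypoxia response genes scyl rose (0.27 ± 0.065), also adjusted over the list alone (list adjusted p = 0.609). Hypoxia genes that rose numbered 0 without RD array 2 or 3 or HFD array 2 or 3. Of 19 ribosome biogenesis genes, 3 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.866), Fib being at 0.39 ± 0.11. The list median was -0.024 and its mean 0.016. Ribosome biogenesis genes that rose numbered 0 without RD array 3 and 1 without RD array 2 or HFD array 1 or 3, and those that fell numbered 0 without RD array 2 or 3 or HFD array 1, 2 or 3 and 2 without RD array 1. Of 14 oxidative stress genes, cnc rose (0.31 ± 0.082) and Sod3 fell (-0.31 ± 0.091), 1 and 2 adjusted over the list alone (list adjusted p = 0.556). Oxidative stress genes that rose numbered 0 without RD array 2 or 3 or HFD array 1, 2 or 3 and 2 without RD array 1, and those that fell numbered 0 without RD array 2 or 3 or HFD array 1, 2 or 3. Of 10 heat shock and chaperone genes, l(2)efl and stv rose and Hsp26 and Hsp27 fell, 3 and 2 adjusted over the list alone (list adjusted p = 0.866). Heat shock genes that rose numbered 1 without RD array 2 or 3 or HFD array 1, 2 or 3, and those that fell numbered 0 without RD array 2 or 3 or HFD array 1 and 1 without HFD array 3. Genes of these lists that rose and fell numbered 1 and 1 (glycolysis), 3 and 0 (ribosome biogenesis), 2 and 1 (oxidative stress) and 2 and 1 (heat shock) with quantile normalization, 0 and 10 (glycolysis), 0 and 3 (hypoxia), 0 and 11 (ribosome biogenesis), 0 and 7 (oxidative stress) and 2 and 5 (heat shock) with median centring, 3 and 7 (glycolysis), 2 and 1 (hypoxia), 5 and 6 (ribosome biogenesis), 3 and 6 (oxidative stress) and 4 and 3 (heat shock) with array weights, and 0 and 0 (glycolysis), 0 and 0 (hypoxia), 0 and 0 (ribosome biogenesis), 0 and 0 (oxidative stress) and 1 and 0 (heat shock) with the control 3'/5' ratio in the model.

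Fold changes differed with the genomic span of genes, a trend tested after the results were seen. With genes in 10 groups by span, 292 of the 866 longest rose and 31 fell, with a median log2 fold change of 0.27. Of the 867 shortest, 68 rose and 93 fell, with a median of -0.060. Spearman's rho across genes, which are not independent replicates, was 0.32, and 0.16 with the control 3'/5' ratio in the model.

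**Figure D4:**
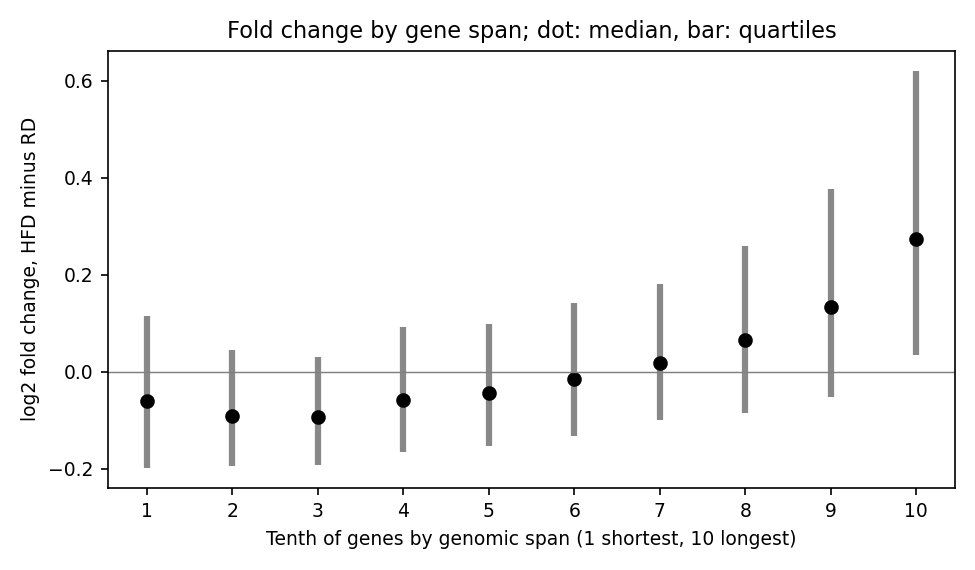
Median log2 fold change, HFD minus RD, of genes in 10 groups by genomic span, with a dot at the median and a bar over the quartiles. The median is -0.060 in the group of shortest genes and 0.27 in that of the longest.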

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

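The tests of gene span, of ovary share, of the eggshell fall in the planned fits that leave out 1 array, and with the 3'/5' ratio in the model were chosen after the results were seen. Some values of control probe sets were higher on all 3 HFD arrays than on all 3 RD arrays. The bioB spike-in controls were 1.70 times higher and those of bioB, bioC and bioD together 1.63 times. The 3'/5' ratio of actin was 1.44 times higher.

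The rise of muscle, neuron and photoreceptor genes goes with these controls, and shorter RNA in the HFD samples may account for some or all of it. With the 3'/5' ratio in the model, the median log2 fold change of the 41 members went from 0.90 (median SE 0.13) to 0.62 (0.15) and the called members from 34 to 15, since estimates shrank and errors grew, so the ratio did not take up the whole rise; it goes together with diet (r = 0.73 over 6 arrays), which makes the correction imprecise. Of 10000 random lists matched on gene span and mean signal, the central range of medians ended at 0.21, so the span trend falls short of the rise. A smaller ovary share would raise markers of other tissues alike. The upper quartile over genes listed for the fat body, midgut, Malpighian tubule and haemocytes was 0.13, under the lower quartile of 0.69 in the pattern. These genes include some that fell in HFD, such as Lsp2, Gnmt and Acbp3, and such falls could hide a rise. The comparison therefore cannot exclude a smaller ovary share. A diet effect on these tissues is a hypothesis that stays open, as do a smaller ovary share and an effect of RNA length. So do differences in when the samples were processed, which the labels do not date.

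The fall of eggshell and yolk genes may come from less ovary RNA in the HFD samples. A uniform loss of ovary would take germline genes down alike, but their lower quartile was -0.18, above the eggshell median of -0.69, and the list mean of eggshell minus germline was 1.45 ± 0.0569 (SD, n = 3) in RD and 0.858 ± 0.105 in HFD. No single array carried the whole fall, since the highest median over the 6 fits that leave out 1 array was -0.46; with array weights, which rest mostly on RD array 3 and HFD array 2, the median was -0.41. With the 3'/5' ratio in the model, the list median went from -0.69 (median SE 0.16) to -0.50 (0.20). The called genes went from 14 to 2, since estimates shrank and errors grew. The ratio did not take up the whole fall in this fit. The correction is imprecise, so the size of an effect of RNA length stays open. Fewer late egg chambers on the diet is a hypothesis that counts of egg chambers would test. Whether it would spare germline genes was not tested.

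Of the 10 splits of the 6 arrays into 3 and 3, 1, the diets, gave 2196 probe sets past the threshold and the highest of the others gave 0; 10 splits are too few for a share under 0.05.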

How the results depend on the processing

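The 3'/5' covariate and the joint omission of RD array 1 and HFD array 1 were chosen after seeing the data. Of 136 named genes past the threshold, 36 kept call and direction in every alternative that held them, and 4 turned in direction in at least 1. The count of 2196 went to 2560 with the replicate block, that is with the array number as a paired factor; deviations from the diet means of same-numbered arrays correlated at 0.072, 0.10 and 0.027 across probe sets, too low to take the numbers as pairs, though RD arrays 1 and 2 correlated best with the HFD array of their own number (RD array 3 with HFD array 2). Outside a factor of 1.5, the count was 4995 with median centring, 1361 with the filter at the 60th percentile, 6129 with array weights, 290 with a log2 fold change of at least 1 and 266 with the 3'/5' covariate; the array weights were uneven, 6.31 for HFD array 2 and 4.91 for RD array 3 against 0.401 to 0.449 for the others. Leaving out 1 array gave 1008 (RD array 3) to 2707 (RD array 1). Probe sets higher in HFD numbered 788 with the filter at the 60th percentile, 3532 with array weights, 212 with a log2 fold change of at least 1 and 213 with the 3'/5' covariate, and 763 to 1867 without 1 array; lower ones numbered 1150 with quantile normalization, 4023 with median centring, 463 without an intensity trend, 2597 with array weights, 1290 at an adjusted p of 0.1, 78 with a log2 fold change of at least 1 and 53 with the 3'/5' covariate, and 245 to 840 without 1 array. The cause was not tested. Of the 10 gene lists past the threshold, none turned in direction, and the call of each was lost with an estimated correlation.

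Values that turned in direction follow, as log2 fold changes of genes or list medians, where a list counts as turned when its test changed direction; the cause was not tested. With median centring, the value was -0.0199 for Idh3a, -0.0336 for mAcon1, -0.0408 for CG5214, -0.0217 for ND-51, -0.163 for RpL32, -0.128 for TCA cycle, -0.181 for male reproductive and -0.201 for ribosomal proteins. With the 3'/5' ratio as a covariate, the value was 0.00176 for FASN1, 0.0350 for fatty acid beta-oxidation, 0.0260 for oxidative phosphorylation, -0.0331 for heat shock and chaperones, 0.0504 for UDP-glycosyltransferase, -0.0197 for hypoxia response and 0.165 for Malpighian tubule. With quantile normalization, the value was 0.0144 for Yp1, -0.109 for fatty acid synthesis, -0.00498 for glycolysis and gluconeogenesis, 0.0259 for oxidative phosphorylation, 0.00620 for ribosome biogenesis and 0.0270 for amino acid metabolism. With array weights, the value was 0.0285 for Yp1 and 0.0152 for bmm. With RD array 1 and HFD array 1 left out together, the value was 0.0310 for bmm, -0.00561 for antimicrobial and immune effector, 0.0898 for midgut and 0.0158 for ribosome biogenesis. With the filter at the 60th percentile, the value was 0.00783 for oxidative phosphorylation, 0.0739 for UDP-glycosyltransferase, -0.0241 for ribosome biogenesis and 0.0173 for amino acid metabolism. With cameraPR on ranks, the value was 3.09e-05 for heat shock and chaperones and 0.0276 for male reproductive. With pseudocount 16, the value was 0.0208 for male reproductive. With pseudocount 50, the value was 0.0133 for male reproductive. With fry in place of camera, the value was 0.0276 for male reproductive and -0.0241 for ribosome biogenesis. With the mean of a gene's probe sets, the value was 0.00750 for ribosomal proteins. Over the 6 fits without 1 array, the ranges were -0.148 to 0.517 for antimicrobial and immune effector, -0.0265 to 0.0756 for male reproductive, -0.0918 to 0.0720 for midgut, -0.00449 to 0.0271 for ribosomal proteins, -0.0810 to -0.00616 for ribosome biogenesis and -0.0358 to 0.0191 for bmm. Of the genes given, Idh3a, mAcon1, CG5214 and ND-51 had passed before they turned, and the ribosomal protein list passed after it did.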

Other observations

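The comparisons of single genes of immunity and of array differences below were chosen after the values were seen. Detoxification and barrier genes were listed too. Of 59 cytochrome P450 genes, 3 rose and 8 fell, also adjusted over the list alone (camera, adjusted p = 0.434), with Cyp4d1 at -0.95 ± 0.20 and Cyp6w1 at -0.87 ± 0.10. With the 3'/5' ratio in the model Cyp4d1 was at -0.71 (adjusted p = 0.256). P450 genes that fell numbered 3 without HFD array 1 and 4 without RD array 2 or 3 or HFD array 2. Of 29 glutathione transferase genes, 2 rose and 5 fell, 3 and 9 adjusted over the list alone (adjusted p = 0.0569), GstE3 being at -0.68 ± 0.089. That list passed without RD array 1 (adjusted p = 0.0369), without the filter (0.0149), with the stricter filter (0.0293), with the replicate block (0.04995) and with RD array 1 and HFD array 1 both left out (0.0454; 0.0149 to 0.747 over the alternatives). Glutathione transferase genes that rose numbered 1 without RD array 2 or 3 or HFD array 3, and those that fell numbered 2 without RD array 2 or HFD array 1, 3 without RD array 3 or HFD array 2, 8 without HFD array 3 and 9 without RD array 1. No UDP-glycosyltransferase gene of 27 passed (adjusted p = 0.645), with Ugt49B1 at -0.45 ± 0.14 and 0 past adjusted over the list alone. UDP-glycosyltransferase genes that rose numbered 1 without RD array 1, and those that fell numbered 2 without RD array 1 or HFD array 3. Cuticle protein genes had 9 of 43 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.101), with Cpr49Ag at 1.09 ± 0.13, and chitin and peritrophic matrix genes 3 higher of 23, also adjusted over the list alone (adjusted p = 0.150), Gasp at 1.42 ± 0.18 and the chitinase gene Cht8 at 0.91 ± 0.092. Without HFD array 3 both lists passed (adjusted p = 0.0114 and 0.0382), and without RD array 3 the cuticle list did (0.0378). Both passed with median centring (0.00628 and 0.0386) though their medians there were -0.019 and -0.023, the cuticle list also with the 3'/5' ratio in the model (0.0183) and the chitin list with fry (0.0284). The range was 0.00628 to 0.747 over the alternatives for cuticle and 0.0284 to 0.491 over the alternatives for chitin. Cuticle genes that fell numbered 0 without RD array 3 and 1 without RD array 2 or HFD array 2 or 3. Chitin genes that rose numbered 5 without RD array 1, and those that fell numbered 1 without RD array 1. Of 24 amino acid genes, 2 rose and 6 fell, 3 and 7 adjusted over the list alone (adjusted p = 0.714), with Gnmt the deepest fall and arg at -0.81 ± 0.21. Amino acid genes that rose numbered 4 without RD array 1, and those that fell numbered 1 without RD array 3 and 2 without RD array 2 or HFD array 1. Genes of these lists that rose and fell numbered 0 and 3 (UDP-glycosyltransferase) and 7 and 7 (cuticle) with quantile normalization, 2 and 19 (P450), 0 and 17 (glutathione transferase), 0 and 6 (UDP-glycosyltransferase), 7 and 7 (cuticle), 3 and 5 (chitin) and 0 and 10 (amino acid) with median centring, 14 and 19 (P450), 7 and 13 (glutathione transferase), 6 and 5 (UDP-glycosyltransferase), 14 and 8 (cuticle), 12 and 3 (chitin) and 9 and 9 (amino acid) with array weights, and 0 and 1 (P450), 0 and 1 (glutathione transferase), 2 and 0 (cuticle) and 1 and 1 (amino acid) with the control 3'/5' ratio in the model.

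The midgut, haemocyte, Malpighian tubule and male reproductive lists did not pass with all 6 arrays. Of 14 midgut genes, 2 rose, pros and Dh31, and 2 fell, CCHa2 and Acbp3, 2 and 3 adjusted over the list alone (adjusted p = 0.630); the median was 0.015 while camera pointed down, and the list passed with the 3'/5' ratio in the model (adjusted p = 0.0342; 0.0342 to 0.984 over the alternatives). Whether the rises of pros and Dh31 came from the midgut was not tested. Midgut genes that rose numbered 0 without RD array 3 or HFD array 2 or 3 and 1 without RD array 2 or HFD array 1, and those that fell numbered 4 without HFD array 3. Of 9 haemocyte genes 1 rose, Pxn, at 1.29 ± 0.18, 2 adjusted over the list alone (adjusted p = 0.213). Of 10 genes listed for the Malpighian tubule, CAP rose (0.55 ± 0.086), also adjusted over the list alone (adjusted p = 0.593). Whether CAP marks that tissue was not tested. Haemocyte genes that rose numbered 2 without RD array 2 and 3 without RD array 1. Of 2 Turandot genes TotZ fell (-0.49 ± 0.12), 2 adjusted over the list alone. Turandot genes that fell numbered 0 without RD array 1, 2 or 3 or HFD array 1 or 2. Marker genes that rose and fell numbered 1 and 5 (midgut), 1 and 1 (haemocyte), 1 and 3 (Malpighian tubule) and 0 and 2 (Turandot) with median centring, 4 and 5 (midgut), 5 and 1 (haemocyte) and 1 and 5 (Malpighian tubule) with array weights, and 0 and 0 (midgut), 0 and 0 (Malpighian tubule) and 0 and 0 (Turandot) with the control 3'/5' ratio in the model.

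The antimicrobial peptide genes Mtk and DptB, chosen after their values were seen, were brightest on HFD array 1: Mtk was at 4650.1, 573 and 1457 on HFD arrays 1, 2 and 3 and at 1146, 373 and 220.0 on RD arrays 1, 2 and 3, and DptB at 1106, 54.6 and 46.6 against 154, 168 and 49.2. Neither passed the test (adjusted p = 0.150 and 0.827). Without HFD array 1 the median log2 fold change of the immune effector list was -0.15, against 0.37 with it, and without RD array 3 it was 0.18.

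RD array 1 differed from the other RD arrays the way HFD did. Across probe sets, the difference of RD arrays 1 and 2 correlated with that of HFD and RD array 3 at r = 0.41, and the difference of RD arrays 1 and 3 with that of HFD and RD array 2 at 0.41; for RD arrays 2 and 3 against RD array 1 it was -0.053.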
